A study of Bifidobacterium breve UCC2003 with 6 samples.

How the data were processed

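Total RNA of *Bifidobacterium breve* UCC2003, an anaerobic gut bacterium, was compared with that of 3 insertion mutants on Agilent arrays that carry both dyes. The mutants were disrupted in lacI1, lacI2 or rafR. Per the labels, all cultures grew anaerobically. The titles and the growth protocol give ribose as the carbohydrate, which other labels of the rafR arrays contradict, as described below. Each mutant was hybridised against the wild type on 2 arrays of opposite dye orientation, which gives 6 arrays in all. Strains and dyes were taken from the strain label of each channel. The labels disagree with themselves in places. The Cy5 source name of 1 lacI2 array names lacI1, while its title and strain label name lacI2. The Cy5 source name of rafR array 1 names the wild type, while its title and strain label name rafR. On both rafR arrays the source names and the carbohydrate labels put Cy3 on raffinose and Cy5 on ribose, whereas the titles and the growth protocol say ribose. The labels do not say whether the arrays of a mutant came from separate cultures, or whether the wild type RNA was shared. The p-values therefore measure the spread between arrays, which may be technical, and if both arrays of a mutant held the same extracts each mutant has 1 biological replicate.

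The deposited scanner files give the intensity of each spot and of its local background in both dyes, made with Agilent Feature Extraction, version 9.5 per the submitters' processing notes and 9.1.1.1 per the file headers. Per the file headers, the log10 ratio of Cy5 over Cy3 in these files was background-subtracted and dye-normalised by Feature Extraction. The series table deposited by the authors holds the same log10 values, in the same direction, with a median of 0 on each array. Other columns, per the file headers, are flags of 0 or 1 per spot for signal well above background, outliers and saturation. Per the labels, differential expression was called by the authors with a Cyber-T test at p under 0.001 and an expression ratio above 3 or under 0.33.

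The arrays hold 10807 spots, of which 544 are controls, and probes of 60 bases for 1843 chromosomal genes, with 3 probes per gene. Of the 5529 chromosomal probes, 4489 have 2 spots and 1040 have 1. Mean spot signals were corrected against the median local background with normexp at an offset of 50. Log2 ratios were then normalised by loess within each array, with controls at weight 0. Outlier spots were left out of the normalisation and of the averages, and no spot was saturated. Spots of a probe were averaged, and a gene's value was the median over its probes. Probes were kept if well above background in at least 1 channel on both arrays of at least 1 mutant, which left 3732 probes and 1366 genes. One of these genes lacked the values for the fit, and 1365 were tested.

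All 6 arrays entered 1 fit in limma 3.58.1 under R 4.3.3, with a coefficient per mutant, coded by dye orientation, and a common dye term. The fit has 2 residual degrees of freedom per gene and a prior of 4.31. Differences between mutants are contrasts of these coefficients. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Values are log2 of mutant over wild type with the standard error (SE). A gene's SE draws on the spread of all 6 arrays, pooled over the mutants, also where n = 2 arrays is given. It may be too small for rafR, whose arrays differed most, and too large for lacI2, whose arrays differed least. Those differences were taken before the dye term was removed, so part of them may be dye bias. Where a gene was not well above background on every array of 1 strain, the change is given as "at least N-fold". That bound sets the mean normalised level of the brighter strain against, on each array, the higher of the dim gene's own level and the lowest level among probes well above background. Levels per channel were taken after loess and Aquantile. Such bounds allow for dim signal but not for the spread between arrays, so they are not lower confidence limits. Where the bound exceeded the fitted fold, as for 1, 1 and 2 called genes of lacI1, lacI2 and rafR, the fitted fold is given instead, a rule chosen after the values were seen.

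The tests, the filter, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the closing section says otherwise. Named genes were the disrupted regulators where the files name them, every called gene with a tag from Bbr_1850 to Bbr_1875, and up to 12 called genes per direction with the largest change and the same sign on both arrays. For contrasts between mutants the 10 called genes with the largest difference were named. Genes named outside this rule were chosen after their values were seen. The files give locus tags without gene products, and 0 of these tags matched the reference gene table, which describes another strain's assembly. The lists defined by product words were therefore not tested, and the disrupted genes were not identified among the tags. One list remained, the tags from Bbr_1850 to Bbr_1875. It was fixed from what is known of the study, so its direction is not independent evidence. It was tested with camera at a preset correlation of 0.01 and with an estimated one. Lists needed at least 5 tested genes.

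The methods' t-test was rerun as Cyber-T on the same gene values, with a window of 101 genes and a prior weight of 10. A separate fit gave the rafR arrays a dye term of their own, to compare their Cy3 and Cy5 channels beyond the dye difference of the lacI arrays. Alternatives covered Agilent's own log ratios, an offset of 0, median centring, no filter or a stricter one, other dye terms, the mean over probes, each mutant's arrays alone, an intensity trend, the series table and leaving out each array in turn. The overlap of calls between mutants was set beside that of independent lists and that of 100 simulated data sets with no effect. In these the mutants shared a wild type that was drawn separately for each replicate.

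The limma fit was tested on simulated data with 200 of 1365 genes changed. At a log2 change of 1 it recovered 92.8% of them for lacI1, 94.1% for lacI2 and 84.7% for rafR. At 3-fold the shares were 98.5%, 98.4% and 97.6%. False calls made up 3.48%, 2.99% and 5.97% of the calls. The simulation changed far more genes than were called in the data and gave a gene the same spread on all arrays. These shares may therefore overstate the recovery in the data. Camera called 5 of 100 unshifted lists of 20 genes. The number of arrays limits the precision of every value.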

Results

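Gene expression was measured in *Bifidobacterium breve* UCC2003 and in its lacI1, lacI2 and rafR insertion mutants. The titles and the growth protocol put all cultures on ribose, while other labels put Cy3 of the rafR arrays on raffinose. The series concerns the regulation of genes for the use of raffinose and melezitose, plant trisaccharides. LacI-type proteins are sugar-responsive transcription regulators, many of which act as repressors. Each mutant was set against the wild type on 2 arrays with the dyes exchanged. The median spot signal of the 4 lacI1 and lacI2 arrays lay between 389 and 477 in Cy3 and between 557 and 737 in Cy5. On the rafR arrays it was 957 and 814 in Cy3 and 1907 and 1551 in Cy5. Their negative controls were brighter too, at 1592 and 1364 in Cy5 against 390 to 479 on the other arrays. Between 26.9% and 65.0% of gene spots were well above background, depending on the array and dye. On the processed log2 scale the tRNA features were brighter on the rafR arrays, 20 of 20, by a median of 0.74. Chromosomal genes differed by -0.03 on that scale, unlike their raw signal above, a baseline that the processing may have set. After turning the dyes, log2 ratios of the arrays of a mutant correlated across genes with Pearson's r of 0.872 for lacI2, 0.403 for lacI1 and 0.209 for rafR. Spearman's rho was 0.676, 0.097 and -0.436. Genes are not independent replicates. The median SD between a mutant's arrays was 0.0801 for lacI2, 0.192 for lacI1 and 0.32 for rafR on the log2 scale. The dye term was not removed for these values, so r, rho and SD mix a gene's dye bias with the spread between arrays. Each mutant had its own slide, and the rafR arrays were scanned on another day than the lacI arrays.

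The first comparison asked which genes respond to disruption of lacI1. A run of neighbouring genes, Bbr_1856 to Bbr_1860, was higher in the mutant than in the wild type. Bbr_1860 was at least 15.6-fold higher (adjusted p = 1.94e-05), Bbr_1858 at least 13.7-fold (adjusted p = 1.94e-05) and Bbr_1859 at least 12.3-fold (adjusted p = 0.000777). Bbr_1857 was at least 2.85-fold higher and Bbr_1856 at least 2.01-fold, with adjusted p of 0.000777 and 0.0039. These are bounds, since the wild type was not well above background on either array. They leave out the spread between arrays, which for Bbr_1859 gave log2 values of 4.17 and 3.06. Outside this run, Bbr_0539 was at least 1.78-fold higher and Bbr_0366 at least 1.94-fold lower, both with an adjusted p of 0.0119; the wild type was above background on 1 of 2 arrays for Bbr_0366. Altogether 7 of 1365 genes were called, 6 higher and 1 lower, and 3 of them exceeded 3-fold by their bounds. The next genes along the tags, Bbr_1861 and Bbr_1862, were not called and were not well above background in either strain. With either lacI1 array left out, 4 genes were called, and the calls of Bbr_1856, Bbr_0539 and Bbr_0366 ended, as they did together with that of Bbr_1857 under Agilent's log ratios and the series table, while Bbr_0539 and Bbr_0366 also lost theirs without a dye term, and Bbr_0366 with the lacI1 arrays alone and by the methods' t-test after Benjamini-Hochberg. With either rafR array left out, 110 genes were called, 80 higher and 30 lower, among them these 7.

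Disruption of lacI2 raised a longer run, Bbr_1856 to Bbr_1862. Bbr_1862 was at least 32.6-fold higher in the mutant (adjusted p = 1.31e-05). Bbr_1858, Bbr_1859, Bbr_1860 and Bbr_1861 were at least 17.7-fold, 17.4-fold, 14.9-fold and 12.7-fold higher, with adjusted p between 1.67e-05 and 0.000263. Bbr_1857 and Bbr_1856 were at least 3.54-fold and 2.6-fold higher, with adjusted p of 0.000409 and 0.000951. In all 7 the wild type was not well above background. Bbr_0539 was at least 2.81-fold higher (adjusted p = 0.0018) and Bbr_0366 at least 2.35-fold lower (adjusted p = 0.00459). Bbr_1722, Bbr_1894 and Bbr_1901 were measured in both strains. Bbr_1722 was higher by 0.91 on the log2 scale (SE 0.12, n = 2 arrays, adjusted p = 0.0307). Bbr_1894 fell by 1.11 (SE 0.15, n = 2 arrays, adjusted p = 0.0283) and Bbr_1901 had a log2 value of -0.88 (SE 0.12, n = 2 arrays, adjusted p = 0.0313). In total 12 genes were called, 9 higher and 3 lower, with 6 beyond 3-fold by their bounds. Agilent's log ratios and the series table ended the calls of Bbr_1856, Bbr_1857, Bbr_1722, Bbr_0366, Bbr_1894 and Bbr_1901. Leaving out the dye term ended the last 4 of these, median centring those of Bbr_1722 and Bbr_1901, and an offset of 0 that of Bbr_1901. Without lacI2 array 1 or array 2 the count was 7 or 6, and the calls of Bbr_0539, Bbr_1722, Bbr_0366, Bbr_1894 and Bbr_1901 ended, as did that of Bbr_1856 without array 2 and those of Bbr_1722 and Bbr_1901 with either lacI1 array left out. With either rafR array left out, it was 131, with 55 higher and 76 lower, including the 12.

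Of the 26 genes on the array with tags from Bbr_1850 to Bbr_1875, 20 were tested. Bbr_1855, Bbr_1865 to Bbr_1868 and Bbr_1872 failed the filter on dim probes. Over all genes, 5 of the tested genes rose in the lacI1 mutant and 7 in the lacI2 mutant. Adjusted over the list alone, 7 were called for lacI1, 6 higher and 1 lower, which adds Bbr_1864, at least 1.59-fold higher with the wild type not well above background, and Bbr_1852 at a log2 value of -0.46. For lacI2 the count adjusted over the list alone was 9, 8 higher and 1 lower, adding Bbr_1863, at least 1.66-fold higher with the wild type again not well above background, and Bbr_1851 at -0.38. The list as a whole shifted up in the lacI2 mutant by camera (adjusted p = 5.18e-05), also with an estimated correlation (adjusted p = 0.0475). In the lacI1 mutant it shifted up with the preset correlation (adjusted p = 0.0195) but not with an estimated one (adjusted p = 0.126). The estimated correlation was -0.0011, below the preset one, so correlation between the genes does not account for the higher p-values. With 1 list tested, adjusted and unadjusted p are equal. The values of the list itself were as follows. The mean log2 change of the list was 0.76 for lacI1 and 1.20 for lacI2, while the medians were -0.06 and -0.03, opposite in sign to the mean and the test. In the rafR mutant limma called 0 of the 20 genes over all genes and 0 adjusted over the list alone, and the methods' t-test called 0 at the authors' thresholds and 0 after Benjamini-Hochberg; 3 had an unadjusted p under 0.05. Their values there ran from -0.65 to 0.24, and camera gave an adjusted p of 0.371, downward, or 0.433 with an estimated correlation. Bbr_1856 to Bbr_1859 and Bbr_1863 were not well above background in either strain on the rafR arrays. For Bbr_1860 and Bbr_1861 the wild type was not. Nor was it for the untested Bbr_1855, Bbr_1865, Bbr_1866, Bbr_1867 and Bbr_1872. A fall in these genes could therefore not be seen, and the value of 0.24 is that of Bbr_1858. The mean in that mutant was -0.06 and the median, of the other sign, 0.01. Without rafR array 1 or array 2, 1 or 2 of the genes were called.

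**Figure D1:**
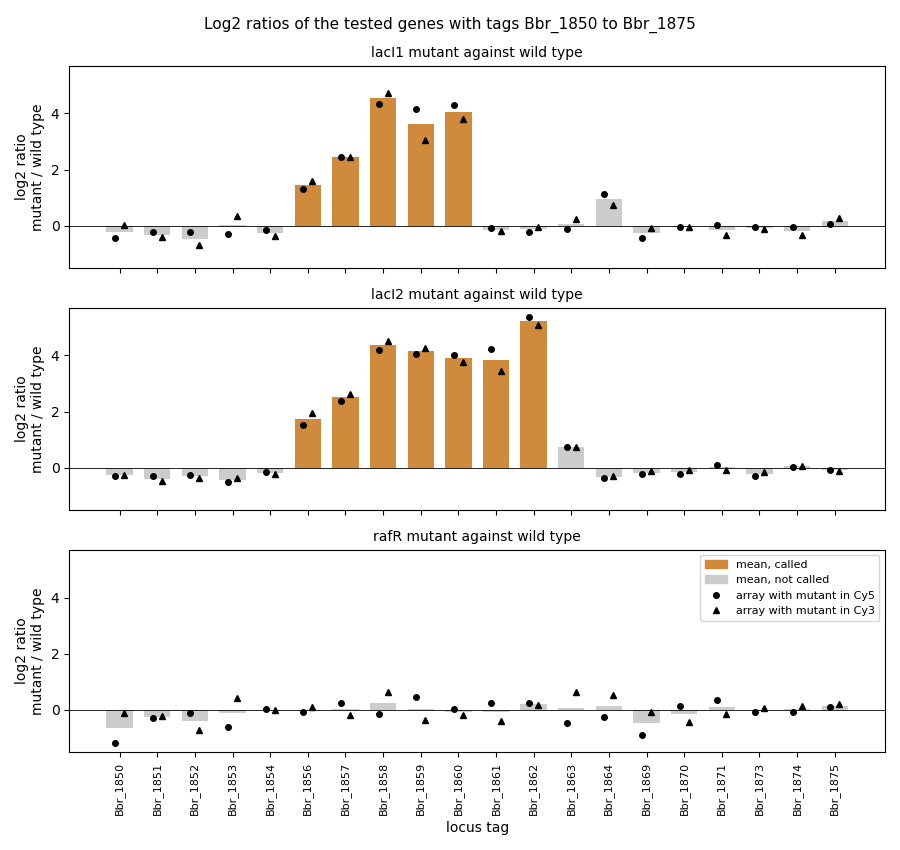
Log2 ratio of mutant over wild type (vertical axes) for each tested gene with a tag from Bbr_1850 to Bbr_1875 (horizontal axis), in the lacI1, lacI2 and rafR mutants. Bars are means of 2 arrays, coloured where the gene was called, and points are single arrays. The run of called genes ends at Bbr_1860 in the lacI1 mutant and at Bbr_1862 in the lacI2 mutant. In the lacI2 mutant Bbr_1863, with 1 probe kept, was also higher on both arrays, each at 0.73, but was not called over all genes. The rafR means stay between -0.65 and 0.24, but Bbr_1856 to Bbr_1859 were not well above background in either strain there. A fall in these genes could not be seen.

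The rafR comparison gave lower expression of genes in 3 groups of neighbouring tags. In the first, Bbr_0118 was at least 45.4-fold lower in the mutant (adjusted p = 3.47e-06), Bbr_0119 at least 11.7-fold (adjusted p = 0.000114), Bbr_0116 at least 5.35-fold and Bbr_0123 at least 5.45-fold (both adjusted p = 0.000117). In the second, Bbr_1847 was at least 36.8-fold lower (adjusted p = 6.94e-06), Bbr_1845 at least 11.6-fold (adjusted p = 0.000119) and Bbr_1843 at least 8.22-fold (adjusted p = 0.000117). Within the third, Bbr_0436 was at least 3.4-fold lower (adjusted p = 0.000504) and Bbr_0439 at least 2.35-fold (adjusted p = 0.000599), the wild type being above background on 1 of 2 arrays for Bbr_0439. Bbr_1844, Bbr_0121 and Bbr_0120 were above background in the mutant on 1 of 2 arrays. Their log2 values were -3.66 (SE 0.15), -3.26 (SE 0.27) and -2.79 (SE 0.14), with adjusted p of 8.28e-05, 0.00114 and 0.000118. With the mutant this dim, these are fitted values and not exact sizes. The mutant level of Bbr_0121, 6.89 on the log2 scale, lay below that of Bbr_0118, 7.44, which is given as a bound. The probes of Bbr_0120 ran from -4.9 to -2.56. The other called genes of these groups were Bbr_0117, Bbr_0435, Bbr_0437, Bbr_0438, Bbr_0440, Bbr_0441 and Bbr_1846. Bbr_0060, Bbr_0366, Bbr_0845 and Bbr_1325 were also called lower. Bbr_0366 was at least 1.61-fold lower, the wild type being above background on 1 of 2 arrays. The arrays of Bbr_0845 gave -3.54 and -0.86 on the log2 scale. Together 23 genes fell, 16 of them beyond 3-fold with dim genes taken at their bounds.

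**Figure D2:**
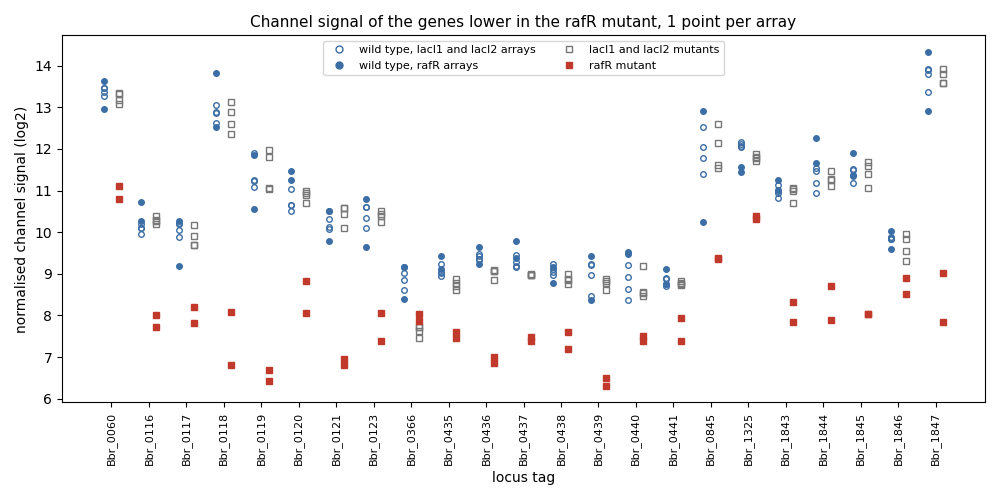
Normalised channel signal (log2, vertical axis) of the 23 genes called lower in the rafR mutant (horizontal axis), 1 point per array and strain. Filled squares are the rafR mutant, filled circles the wild type on the same arrays, and open symbols the strains on the lacI1 and lacI2 arrays; the level of the rafR mutant minus that of the lacI mutants has a median of -2.37 over the genes.

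Higher expression in the rafR mutant was called for 5 genes. Bbr_0890, Bbr_0891 and Bbr_0892, which neighbour each other, were higher by 1.45 (SE 0.17), 1.35 (SE 0.16) and 1.24 (SE 0.16) on the log2 scale, with adjusted p of 0.00651, 0.00644 and 0.00883, the wild type being above background on 1 of 2 arrays for each. Their sizes are therefore fitted values and not exact. Bbr_0539 was at least 2.11-fold higher (adjusted p = 0.00154) and Bbr_1722 higher by 0.81 (SE 0.12, adjusted p = 0.0256). These bring the count for rafR to 28. With Agilent's processed log ratios 19 of the 28 genes were called, 0 of them higher. The calls of Bbr_0439 and of the 5 higher genes ended, and so did some other lower calls. Those of the 5 higher genes also ended by the methods' t-test after Benjamini-Hochberg. With the rafR arrays alone 20 of the 28 stayed called, 1 higher and 19 lower. The calls of Bbr_0891, Bbr_0892, Bbr_0539 and Bbr_1722 ended, as did some lower calls. That of Bbr_1722 also ended with median centring or with either lacI1 array left out. Without rafR array 1 the count was 128, with 88 higher and 40 lower, and without rafR array 2 it was 87, with 11 higher and 76 lower, each including the 28.

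The mutants were compared with each other to ask whether their effects differ. The effects of lacI1 and lacI2 differed in 2 genes of 1365. Bbr_1862 was lower in the lacI1 effect, with a fitted log2 difference of -5.36 (95% interval -5.83 to -4.90, adjusted p = 9.88e-05) and so was Bbr_1861, with -3.98 (95% interval -4.50 to -3.45, adjusted p = 0.00071). For the 5 genes raised in both, the differences were not called. Their 95% intervals were -0.69 to 0.14 for Bbr_1856, -0.57 to 0.45 for Bbr_1857, -0.29 to 0.65 for Bbr_1858, -1.31 to 0.23 for Bbr_1859 and -0.26 to 0.59 for Bbr_1860. The wild type was not well above background for any of these 7 genes, nor the lacI1 mutant for Bbr_1861 and Bbr_1862, so the differences and intervals are those of fitted values and not exact sizes. With either rafR array left out, 34 genes were called, 29 higher and 5 lower, including both.

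The rafR effect differed from that of lacI1 in 29 genes, 3 higher and 26 lower, and from that of lacI2 in 31 genes, 5 higher and 26 lower. Against lacI1 the fitted log2 differences were -5.87 for Bbr_0118 and -5.31 for Bbr_1847, and -4.30 for Bbr_1858 and -4.15 for Bbr_1860, which lacI1 disruption raised. Against lacI2, the fitted differences were -5.41 for Bbr_0118, -5.07 for Bbr_1847 and -5.03 for Bbr_1862. In each of these genes the rafR mutant or the wild type was not well above background, so the values give neither exact sizes nor an order. Bbr_0122 had a log2 value of -1.69 in the rafR mutant, which was not called there (adjusted p = 0.0619) but was in 8 of 18 other settings. The value was -0.82 without rafR array 1 and -2.55 without rafR array 2, each strain being above background on 1 of 2 arrays. It differed from its lacI1 value of 1.23 (difference -2.92, adjusted p = 0.0273), a call made in 12 of 15 other settings, with differences from -3.81 to -2.06. Slide and scan day cannot be told apart from the mutant in these contrasts, although each array carries both strains. The count against lacI1 was 68 without rafR array 1, with 34 higher and 34 lower, and 121 without rafR array 2, with 17 higher and 104 lower. Against lacI2 it was 124, with 85 higher and 39 lower, and 66, with 13 higher and 53 lower, and 19 without lacI2 array 1.

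Calls were shared between mutants. The lacI1 and lacI2 mutants shared 6 higher genes, Bbr_1856 to Bbr_1860 and Bbr_0539, where independent lists would share 0.0396. They shared 1 lower gene, Bbr_0366, against 0.0022. Bbr_1722 was called higher in the lacI2 and rafR mutants. In the main fit Bbr_0539 was higher and Bbr_0366 lower in all 3 mutants. Each of the 6 arrays showed the same sign after turning the dyes, which calling on the turned mean favours. Both genes lost their lacI1 calls under Agilent's log ratios, the series table and without a dye term. The rafR call of Bbr_0366 was close to the threshold (limma adjusted p = 0.0406), with arrays at -1.11 and -0.37. In simulations with no effect, the mutants shared a wild type that was drawn anew for each replicate. Pairs of mutants shared at most 0.02 genes on average in 100 draws and at most 2 in a single draw, the number that lacI1 and rafR shared. A single wild type RNA on all 6 arrays was not simulated, so these values do not bear on it. Part of the sharing may come from a shared wild type, which the labels do not settle.

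The methods' t-test at the authors' thresholds called 4 genes for lacI1, Bbr_1857 to Bbr_1860, 7 for lacI2, Bbr_1856 to Bbr_1862, and 16 for rafR, each lower in the mutant. All of these were also called by limma. After Benjamini-Hochberg adjustment the methods' t-test called 8, 417 and 18 genes.

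Because labels of the rafR arrays name raffinose for Cy3 and ribose for Cy5, the channels of those arrays were compared beyond the dye difference of the lacI arrays. In limma 84 genes were called, 79 higher in Cy3 and 5 lower, and 0 of these exceeded 3-fold. Bbr_0985 was among those higher in Cy3 (adjusted p = 9.15e-08) and was not well above background in Cy5 on either rafR array. None of the 20 tested genes from Bbr_1850 to Bbr_1875 was called, with differences from -0.32 to 0.49. The fit has 1 residual degree of freedom and an infinite prior, so its SE is common to all genes. By this fit 272 genes had an unadjusted p under 0.05. Median centring gave 8 called genes, and Agilent's log ratios or the rafR arrays alone gave 0.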

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

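The tests of explanations in this part were chosen after the result was seen, except that of probe GC content.

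The effects of the mutants differed from each other by the test of the difference itself, in 2 genes between lacI1 and lacI2, in 29 between rafR and lacI1 and in 31 between rafR and lacI2. The log2 differences below are fitted values. In most of these genes a strain was not well above background, so they give neither exact sizes nor an order. Between lacI1 and lacI2 they were -5.36 for Bbr_1862 and -3.98 for Bbr_1861, which were raised in the lacI2 mutant. Between rafR and lacI1, genes lower in the rafR mutant gave -5.87 for Bbr_0118, -5.31 for Bbr_1847, -4.80 for Bbr_0119, -3.54 for Bbr_1845, -3.49 for Bbr_1844, -3.28 for Bbr_0121 and -2.93 for Bbr_1843. Genes raised in the lacI1 mutant gave -4.30 for Bbr_1858, -4.15 for Bbr_1860 and -3.57 for Bbr_1859. Between rafR and lacI2, the first kind gave -5.41 for Bbr_0118, -5.07 for Bbr_1847, -4.47 for Bbr_0119, -3.80 for Bbr_1845 and -3.71 for Bbr_1844. Genes raised in the lacI2 mutant gave -5.03 for Bbr_1862, -4.12 for Bbr_1858, -4.11 for Bbr_1859, -3.98 for Bbr_1860 and -3.90 for Bbr_1861.

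The 23 genes lower in the rafR mutant might reflect an unusual wild type, but the wild type level on the rafR arrays differed from that on the lacI arrays by a median of -0.041. The rafR mutant lay below the lacI mutants in 22 of the 23, by a median of -2.37, and 23 were still called lower after a trend on probe GC content was removed. A sugar difference between the channels that acts alike in both strains would turn sign between the rafR arrays, whereas the 20 genes over 3-fold lower on array 1, 17 of them among the 23, had a median of -2.24 on array 2, with 19 lower, and 16 of 16 chosen on array 2 were lower on array 1. High background stays open for some, since 19 of the 23 were well above background in the wild type on both rafR arrays. A lower level caused by loss of rafR is a hypothesis that stays open beside it.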

How the results depend on the processing

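The fit of the lacI arrays alone was chosen after the data were seen. No named gene changed direction in any setting run, and 3 of 7 named genes for lacI1, 5 of 12 for lacI2 and 11 of 17 for rafR were called in every setting that tested them, as were the 2, 10 and 10 genes named in the contrasts. Counts moved more. With Agilent's log ratios, and equally with the series table, 3 genes were called for lacI1 (3 higher, 0 lower, against 6 and 1), 7 for lacI2 (7 and 0, against 9 and 3), 19 for rafR (0 and 19, against 5 and 23), 19 for rafR against lacI1 (0 and 19, against 3 and 26) and 20 for rafR against lacI2 (0 and 20, against 5 and 26). The region list then had 3 calls for lacI1. The stricter filter gave 37, 61 and 13 calls for lacI1, lacI2 and their difference, and 1, 0 and 2 region genes for lacI1, lacI2 and rafR. None of the 7 genes called for lacI1 could be tested under that filter, which their dim wild type or mutant signal fails. With no filter rafR had 44 calls and 1 region gene. That gene, Bbr_1866, was at least 1.09-fold higher in the mutant (limma adjusted p = 0.0274). The mutant was above background on 1 of 2 arrays for it and the wild type on 0. The region list then turned upward in rafR by camera (adjusted p = 0.908). An own dye term for the rafR arrays gave 110 calls for lacI1, 131 for lacI2, 100 for rafR, 34 for lacI1 against lacI2, 85 and 80 for rafR against lacI1 and lacI2, and 3 region genes for rafR. The lacI arrays alone gave 110, 131 and 34. These fits have 1 residual degree of freedom and an infinite prior, with the same median SE of 0.138. Their SE is common to all genes and does not reflect the spread of a gene's own arrays. Leaving out a rafR array gives the lacI counts of the same fit, since the other rafR array then sets its own coefficient. Each mutant's arrays alone gave 269 calls for lacI2 and 12 region genes. Cyber-T at the authors' thresholds gave 4, 7 and 16 calls. After Benjamini-Hochberg it gave 8, 417 and 18, with 14 region genes for lacI2. The region list in lacI1 lost its call with an estimated correlation (adjusted p = 0.126) and median centring (adjusted p = 0.13). The channel comparison of the rafR arrays, 84 calls, gave 8 with median centring and 0 with Agilent's log ratios or the rafR arrays alone. Leaving out 1 array at a time gave 4 to 110 calls for lacI1, 6 to 131 for lacI2, 27 to 128 for rafR, 2 to 34 for lacI1 against lacI2, 20 to 121 for rafR against lacI1 and 19 to 124 for rafR against lacI2. It gave 4 to 7, 6 to 9 and 0 to 2 region genes for lacI1, lacI2 and rafR, and adjusted p of 1.55e-20 to 0.0709, 3.06e-41 to 0.000247 and 0.355 to 0.788 for the region list. The call for lacI1 ended with either lacI2 array left out (adjusted p = 0.0709). Unless stated, the cause was not tested. Each array pairs a mutant with the wild type, and the fit used the ratio within each array. The labels carry no replicate numbers, so arrays of different mutants were not paired with each other. Signal over background limits the folds to bounds for 6 of 6 called genes higher and 1 of 1 lower in lacI1, 8 of 9 and 1 of 3 in lacI2, and 1 of 5 and 16 of 23 in rafR.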

Other observations

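The tests of shared genes, of neighbouring tags and of explanations for the channel difference were chosen after the result was seen, as was the fit of the lacI arrays alone.

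Without the filter on dim probes, further genes near the group from Bbr_0435 to Bbr_0441 passed the threshold as lower in the rafR mutant, none of them well above background in the mutant. Bbr_0448 was at least 1.44-fold lower (adjusted p = 0.0225), Bbr_0447 at least 1.21-fold (adjusted p = 0.0185) and Bbr_0461, further along, at least 1.12-fold (adjusted p = 0.00244), the wild type being above background on 1 of 2 arrays. No fold is given for Bbr_0434, which has no bound above 1, or for Bbr_0445, Bbr_0446 and Bbr_0449, where neither strain was well above background. Bbr_1855, next to the raised run, was at least 2.21-fold higher in the lacI2 mutant (adjusted p = 0.00384), with the mutant above background on 1 of 2 arrays and the wild type on 0.

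In the 4 lacI arrays fitted alone, 21 genes were higher in both lacI mutants, where independent lists would share 3.22, and 4 were lower in both, against 1.67. A run of Bbr_0515, Bbr_0516 and Bbr_0517 was among them, at 0.67, 0.61 and 0.58 for lacI1 and 0.47, 0.45 and 0.51 for lacI2. Bbr_0122 was higher by 1.23 and 0.73. Bbr_0538, next to Bbr_0539, was also called higher in both, with the wild type not well above background. These calls, among 110 and 131, were made with 1 residual degree of freedom and an infinite prior. Each gene thus had the same SE, whatever the spread of its own arrays. A wild type RNA shared by the arrays could give part of this sharing, which was not tested for this fit.

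Genes called in the rafR mutant lay next to each other along the locus tags, with 17 pairs of adjacent tags. Random sets of 28 tested genes held 0.448 such pairs on average and at most 5 (permutation p = 1e-05, the smallest that these sets can give). A shared transcript is a candidate explanation for the 17 pairs and was not tested.

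Bbr_0539 and Bbr_0366 were called the same way in all 3 mutants in the main fit, though not in every setting. The smallest change over the 6 arrays in the called direction was 0.37, for Bbr_0366 on rafR array 2. This cannot decide against a dye or single-array artefact, since genes called the same way on dye-turned means mostly share their sign already. Independent lists would share 0.000182 genes, but the 3 lists come from 1 fit. One wild type RNA on all arrays could give the same pattern, and the range of 0.36 between the 3 effects on Bbr_0539 does not separate this from a change common to the mutants.

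The Cy3 to Cy5 difference of the rafR arrays may be a dye bias of dim genes, since the called genes were dimmer than the others by a median of -0.48 in mean log2 intensity. Growth of the Cy3 cultures on raffinose would raise Cy3 over Cy5 if raffinose raises the tested genes from Bbr_1850 to Bbr_1875 alike in both strains. The largest difference among these tested genes, 0.49, argues against that case alone. The comparison averages over both strains, has 1 residual degree of freedom and leaves out the genes that failed the filter. Whether raffinose raises these genes was not tested. A sugar difference with other target genes was not tested.

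Among 45 other features, 20 were tested and limma called 0 in each mutant, with 0, 2 and 1 at an unadjusted p under 0.05 for lacI1, lacI2 and rafR.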
